A study of Streptomyces coelicolor A3(2) with 3 samples.

How the data were processed

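The data are 3 two-colour Agilent arrays of Streptomyces coelicolor A3(2), each with cRNA of the ohkA mutant labelled with Cy5 and cRNA of wild-type M145 labelled with Cy3, at 48, 64 and 88 h, per the labels' protocols. Groups were taken from the sample titles and genotypes; each array is its own group with 1 sample. The arrays were read with Agilent Feature Extraction, per the submitters' processing notes; its version, background method and dye normalization are not given in the sources used here.

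The deposited tables, per the file headers, hold for each spot the ratio of mutant over wild type, the p-value of the log ratio from the scanner software, and for each channel a signal intensity, a normalized signal intensity, a signal-to-noise score and another column of spot flags. The deposited ratio equals the quotient of the normalized intensities. The tables hold no background column, and signals near 0 show that background had already been subtracted, so the planned background correction could not be run as designed; the deposited signal intensities were used with the planned offset. The meaning of the deposited flags is not stated; flag 2 occurred only in the wild-type channel, on dim spots. The authors' series table, deposited as log2 values, equals log2 of these ratios to within 5e-10, uncentred; for 64 h this holds through the spot numbers of the 48 h array, while by the 64 h table's own numbers the largest difference was 6.87. Its direction is mutant over wild type, and its medians were 0.02, 0.04 and 0.07 at 48, 64 and 88 h. The 64 h array numbers its spots differently from the others, so arrays were joined by probe name.

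Each array has 14969 spots. Of 7734 genes, 7491 were named in the files and 243 were matched by the end coordinate of the target; 7470 have a locus tag in the RefSeq table of assembly ASM20383v1. 7235 genes have 2 spots and 499 have 1. The probes of 22 genes match several genes.

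From the signals, log2(signal + 50) was taken in both channels, the log2 ratio was loess-normalized within each array (span 0.3, 4 iterations), and the spots of a gene were averaged. A gene was counted where its signal-to-noise score was above 2.6 in at least 1 channel, a stand-in for the scanner's own background flag; this removed no gene. For the test over the 3 arrays, a gene had to pass on at least 2. In the wild-type channel 151, 66 and 14 genes were not above it at 48, 64 and 88 h, of which 3, 1 and 0 counted as at least 2-fold higher in the mutant; their ratios are lower bounds, and no gene named in the texts is among them. The offset of 50 pulls ratios of dim genes toward 0.

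With 1 array per time, single times were compared by a size rule (log2 ratio of at least 1 in size) without p-values. Over the 3 arrays, limma 3.58.1 in R 4.3.3 (lmFit and eBayes) tested the mean log2 ratio against 0, two-sided, with Benjamini-Hochberg adjustment over 7734 genes; the prior had 2.44 degrees of freedom and an SD of 0.20. On simulated data for this comparison, limma recovered 54 of 100 genes changed by a log2 of 1 and 92 of 100 changed by 2, with 10 false calls among 7534 unchanged genes. The simulated arrays were independent draws from limma's own model, with no dye effect and no time closer to one than to another. They do not show how many of the real calls are false. The standard errors printed are limma's moderated ones. For 27 gene lists fixed beforehand, the median log2 ratio was set among 10000 random lists of the same size, matched by mean brightness in 10 bins. Of 200 random lists of 12 genes tested in this way, 11 lay outside the middle 95%. Channels were compared between arrays after loess and Aquantile. Other tools were Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.

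Genes were named by a rule set before the data were examined: ohkA; the 10 highest and 10 lowest at each time among genes at least 2-fold different with all spots in one direction; the 10 highest and 10 lowest means past limma; up to 4 members of each list with the largest ratio at each time; and a set list of regulators. Other genes are said to be chosen after their values were seen. The report also names whiD and pheS, which the rule did not pick. The alternatives tried were the scanner's log ratio, the series table, an offset of 10 or 0, median centring in place of loess, no filter, both channels above background, the median of spots, the scanner's p-value, leaving out flagged spots, leaving out each array, time as a covariate, an intensity trend with robust fitting, an adjusted p under 0.1, and quantile normalization of the 6 channels.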

Results

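Streptomyces coelicolor A3(2) M145 is a filamentous soil bacterium that grows as branching substrate hyphae, raises aerial hyphae, turns these into chains of grey spores and makes several antibiotics, among them the blue actinorhodin and the red undecylprodigiosin. The series compared M145 with a mutant that lacks ohkA (SCO1596), the gene of an orphan histidine kinase, a sensor kinase whose partner response regulator is not encoded beside it. Both strains grew on solid MS medium under cellophane, and RNA was taken at 48, 64 and 88 h. The question was which genes respond to the loss of ohkA at each of these times. Each time was measured on 1 Agilent array, with the mutant in the Cy5 channel and the wild type in the Cy3 channel, so there were 3 arrays, no replicate culture at any time and no array with swapped dyes. Each array held 14969 spots for 7734 genes. The median signal of the mutant channel was 1146, 1619 and 2718 at 48, 64 and 88 h, and that of the wild-type channel 584, 709 and 1086. The median SD between the 2 spots of a gene was 0.06 at 48 h, 0.05 at 64 h and 0.05 at 88 h on the log2 scale. This is the technical error within an array; the spread between cultures is unknown, and the number of arrays limits the precision. All ratios below are log2 of mutant over wild type, given in the order 48, 64 and 88 h. The adjusted p after the ratios of a gene is limma's, for their mean over the 3 arrays, and a gene passed if it was under 0.05. A gene said to rise or fall is one that passed with a mean above or below 0, which is not a trend over time. The percentile of a gene list's median is its place among 10000 random lists of the same size and brightness, as a description of these libraries. Medians with median centring of each array in place of loess follow where they differ in sign or at least 1.5-fold in size at any time. Genes are named by their locus tags, with chromosome coordinates of assembly ASM20383v1 as in the files.

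The deleted gene came out far lower in the mutant on every array. The log2 ratio of ohkA (SCO1596, complement strand, 1708109 to 1709248, a coding sequence) was -3.51 ± 0.01 at 48 h, -3.35 ± 0.04 at 64 h and -3.59 ± 0.01 at 88 h (SD between 2 spots). Its wild-type signal was 1567, 985 and 1292 at the 3 times, against 239.6, 197 and 255 in the mutant channel. The extent of the deletion is not given in the sources used here, so whether the probe lies inside it is not known.

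Of all means over the 3 times that passed limma, the lowest was that of an aerial hyphal surface gene and the highest that of an actinorhodin gene. The rodlin gene rdlA (SCO2718) had a mean log2 ratio over the 3 times of -5.85 ± 0.22 (moderated SE, n = 3 arrays, limma adjusted p = 0.00202, lower on 3 of 3 arrays), and the actinorhodin gene actVA (SCO5080) had 4.0 ± 0.24 (limma adjusted p = 0.00307, higher on 3 of 3). At 48 h, 557 genes were at least 2-fold higher and 635 at least 2-fold lower in the mutant. At 64 h these were 481 and 758, and at 88 h 407 and 841. Of these, 233 genes were at least 2-fold higher at all 3 times and 279 at least 2-fold lower at all 3. The balance of higher and lower genes depended on the scaling. With the scanner's own log ratio 732 and 716 genes were higher and lower at 48 h, 655 and 777 at 64 h and 602 and 805 at 88 h; with median centring these were 599 and 840, 461 and 907 and 381 and 1135. The share of higher genes at 88 h was 32.6%, 42.8% with the scanner's log ratio and 25.1% with median centring.

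With the 3 times taken as samples of one contrast, 1912 genes were higher and 1786 lower by limma (mean against 0, two-sided, adjusted p under 0.05, 7734 genes tested). These are large shares of all genes, so a list drawn at random would also hold members that passed in each direction. The counts of list members that rose or fell are to be read against these shares. A mean of at least 2-fold was reached by 408 of the higher and 565 of the lower genes. Without the 64 h array the counts of higher and lower genes were 53 and 91, and without the 88 h array 984 and 896. A fit on 2 arrays takes a gene's own spread from the difference between the times kept, 48 h and 88 h in the first case. The p-values measure only the spread between 3 arrays of different times, and a dye effect of a gene is part of each ratio. Across genes, which are not independent replicates, the log2 ratios of 64 h and 88 h correlated with Pearson's r = 0.900, those of 48 h and 64 h with r = 0.754 and those of 48 h and 88 h with r = 0.669.

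**Figure D1:**
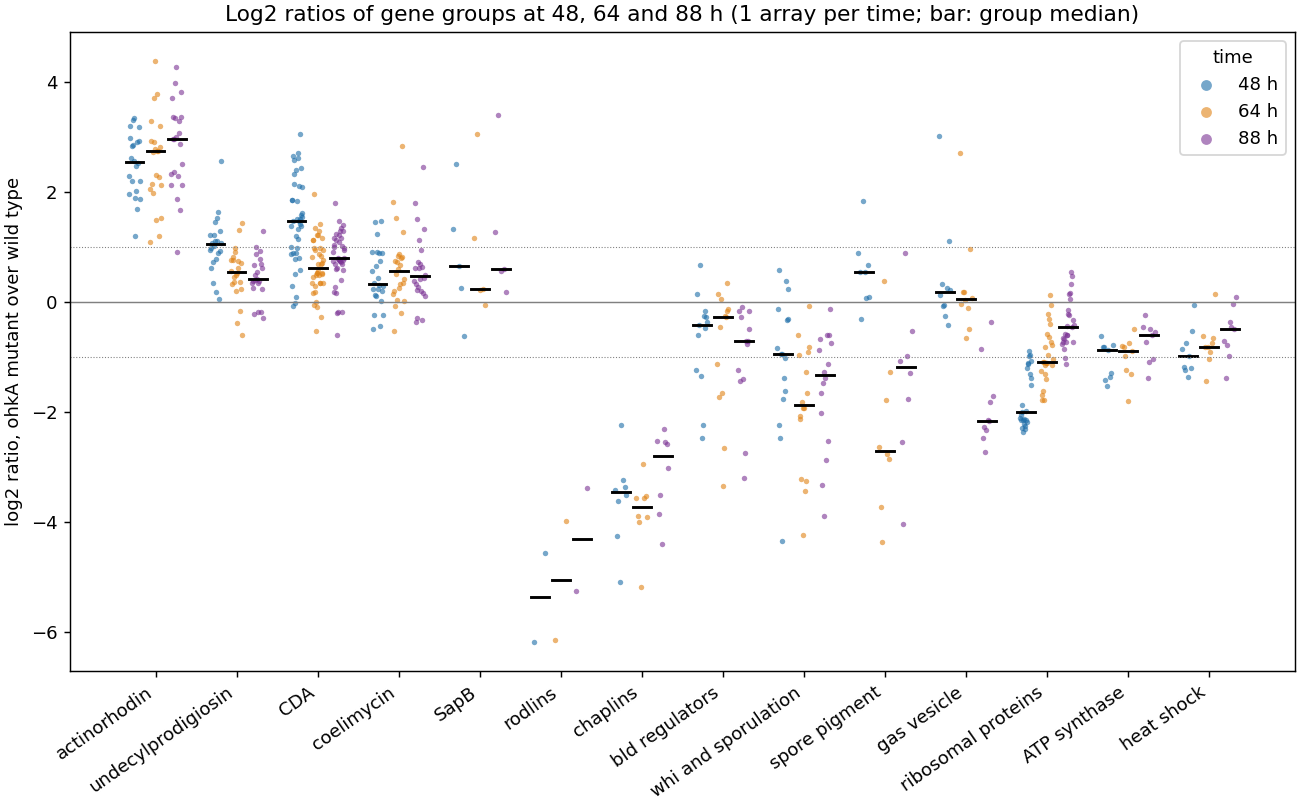
Log2 ratio of mutant over wild type (vertical axis) of every member of 14 gene groups (horizontal axis), with 1 point per gene, 1 colour per time and a black bar at the group's median; dotted lines mark a 2-fold difference. The actinorhodin medians lie between 2.54 and 2.96 and the chaplin medians between -3.72 and -2.80, while the spore pigment median is 0.55 at 48 h and -2.70 at 64 h.

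The actinorhodin cluster (5513809 to 5535091) was higher in the mutant as a block. Of its 22 genes, 22, 22 and 21 were at least 2-fold higher at 48, 64 and 88 h, with medians of 2.54, 2.74 and 2.96 (percentiles 100, 100 and 100; 1.77, 1.94 and 1.65 with median centring). Each median was above all 10000 random lists. All 22 rose by limma over the 3 times, and as many adjusted over the list alone; 21 did so without the 64 h array. The activator gene actII-ORF4 (SCO5085), which encodes the switch for the cluster, had log2 ratios of 2.48 at 48 h, 3.79 at 64 h and 3.08 at 88 h (mean 3.11 ± 0.27, limma adjusted p = 0.00443). The highest mean was that of actVA (SCO5080), with 3.34, 4.37 and 4.27 (adjusted p = 0.00307), followed by SCO5079 with 3.30, 3.70 and 3.98 (adjusted p = 0.00204). The acyl carrier protein SCO5089 of the polyketide synthase had 3.17, 3.20 and 3.82 (adjusted p = 0.00254).

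**Figure D2:**
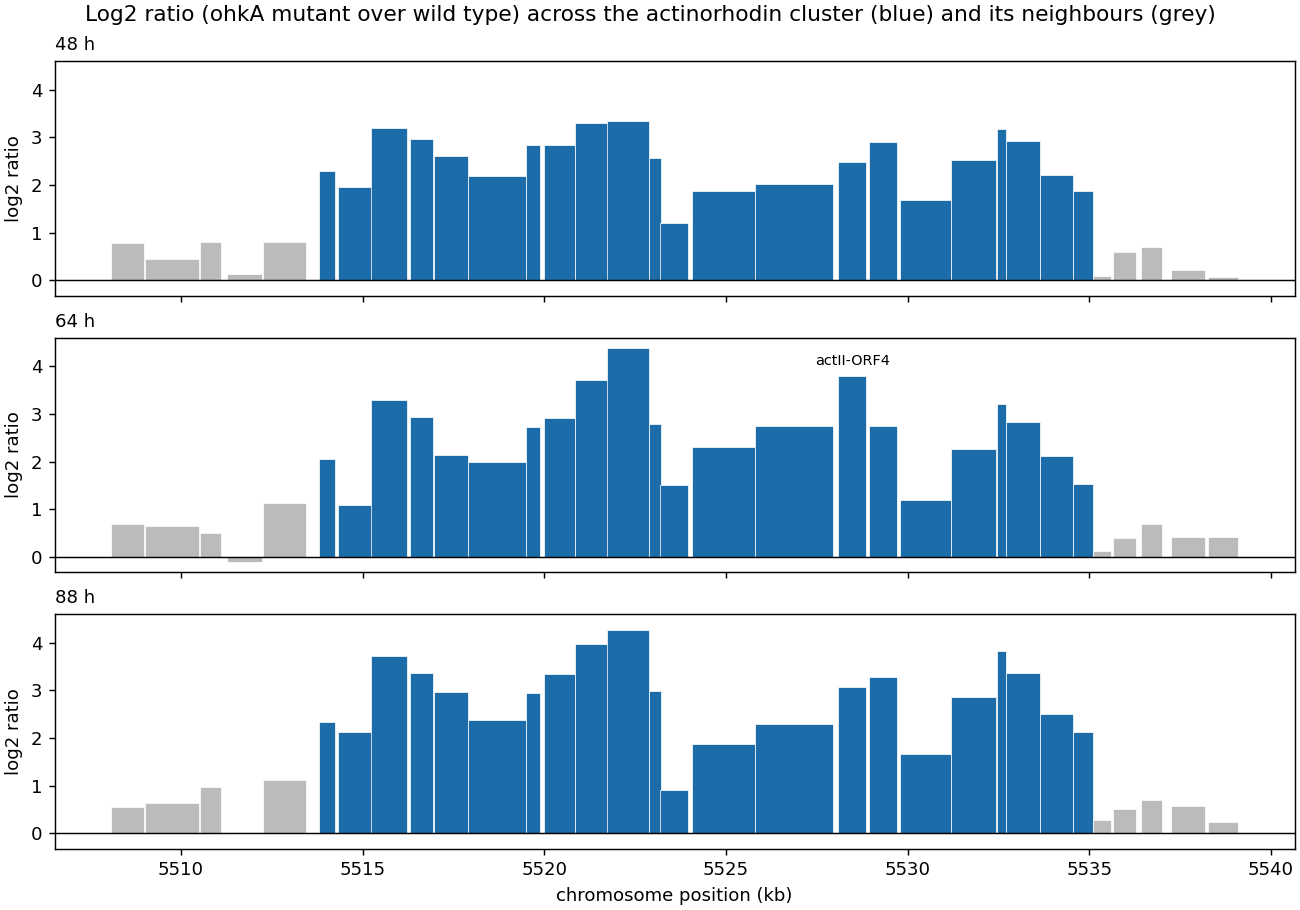
Log2 ratio of mutant over wild type (vertical axis, 1 array per panel) against chromosome position in kb (horizontal axis); each bar spans 1 coding sequence, blue for the 22 actinorhodin genes and grey for neighbours. At 48 h the blue bars lie between 1.21 and 3.34, and at 88 h between 0.91 and 4.27.

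The other antibiotic clusters were higher by less. In the cluster of undecylprodigiosin (6432566 to 6464206), 12, 2 and 1 of 22 genes were at least 2-fold higher at 48, 64 and 88 h, and the medians were 1.05, 0.55 and 0.41 (percentiles 100, 99.98 and 99.56). By limma 16 of its genes rose, also adjusted over the list alone, and 6 did not pass; 0 passed without the 64 h array and 8 without the 88 h array. SCO5897 was the highest at each time (2.57, 1.44 and 1.29, adjusted p = 0.0115). The pathway activator redD (SCO5877) had 1.22, 0.57 and 0.34 (mean 0.71 ± 0.20, limma adjusted p = 0.0428), and redZ (SCO5881), which did not pass, had 1.07, 0.81 and -0.22 (adjusted p = 0.162). For the calcium-dependent antibiotic, a lipopeptide encoded at 3519449 to 3602320, the counts of genes at least 2-fold higher were 27, 9 and 14 of 40, with medians of 1.47, 0.62 and 0.79 (percentiles 100, 100 and 100). By limma 32 of them rose, also adjusted over the list alone, but 0 without the 64 h array and 13 without the 88 h array. Its activator cdaR (SCO3217) had 1.47, 0.99 and 0.70 (adjusted p = 0.0123) and SCO3218 2.65, 1.97 and 1.80 (adjusted p = 0.00462), while the myo-inositol phosphate synthase SCO3243 had 3.04, 0.70 and 1.40 (adjusted p = 0.0418). The coelimycin cluster (6890528 to 6948414), which holds the butyrolactone signalling genes, had medians of 0.33, 0.56 and 0.46 (percentiles 98.4, 99.99 and 99.84; 0.52, 0.59 and 0.48 with median centring); 12 of 24 genes rose and 1 fell by limma (16 higher and 2 lower adjusted over the list alone), and 0 passed without the 64 h array and 8 without the 88 h array. Among them were scbA (SCO6266), the butyrolactone synthase gene, with 0.91, 1.81 and 1.80 (adjusted p = 0.00924), SCO6284 with 1.47, 2.83 and 2.46 (adjusted p = 0.00728) and the activator cpkO (SCO6280) with 0.89, 0.68 and 0.95 (adjusted p = 0.00696). The receptor gene scbR (SCO6265) did not pass (0.56, 0.14 and 0.39, adjusted p = 0.0664), nor did scbR2 (SCO6286), with 0.20, 0.34 and 0.44 (adjusted p = 0.0525). The probes of SCO6269, counted among the coelimycin genes that rose, and of SCO6270, which did not pass, each match 2 genes.

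The genes of the hydrophobic coat of aerial hyphae fell. All 8 chaplin genes, whose proteins assemble at the hyphal surface, were at least 2-fold lower at each time and fell by limma, also adjusted over the list alone; 8 passed without the 64 h array and 8 without the 88 h array. The chaplin medians were -3.45, -3.72 and -2.80 (percentiles 0, 0 and 0) and the rodlin medians -5.36, -5.06 and -4.31 (percentiles 0, 0 and 0). The lowest chaplin gene was chpD (SCO2717), with -5.09 at 48 h, -5.18 at 64 h and -4.39 at 88 h, a mean fold of 29.6 lower. The chaplin genes chpB (SCO7257) and chpC (SCO1674) had -4.26, -3.89 and -3.85 (adjusted p = 0.00202) and -3.62, -3.99 and -3.51 (adjusted p = 0.00202), and chpH (SCO1675) had -3.50, -3.90 and -3.02 (adjusted p = 0.00296). Of the rodlin genes, which form the rodlets on that surface, rdlA (SCO2718, 2961619 to 2962014) had -6.17, -6.14 and -5.25 (adjusted p = 0.00202) and rdlB (SCO2719) -4.55, -3.97 and -3.37 (adjusted p = 0.00315); both fell by limma, also adjusted over the list alone. The ram cluster (7419664 to 7427004), which makes the surface peptide SapB, went the other way in part, with medians of 0.66, 0.24 and 0.59 (percentiles 98.2, 76.5 and 96.5; 0.72, 0.41 and 0.78 with median centring). Its precursor gene ramS (SCO6682) had 2.51, 3.05 and 3.40 (mean 2.99 ± 0.19, limma adjusted p = 0.00353) and the modifying enzyme gene ramC (SCO6681) had 1.32, 1.17 and 1.28 (adjusted p = 0.00376). Of 5 members 3 rose (4 higher and 0 lower adjusted over the list alone), and 1 did so without the 64 h array and 2 without the 48 h or the 88 h array; the regulator gene ramR (SCO6685) did not pass, with -0.62, -0.06 and 0.18 (adjusted p = 0.486).

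Several developmental regulators fell with them. The lowest was wblA (SCO3579), a WhiB-like regulator needed for sporulation, with -4.34 at 48 h, -4.22 at 64 h and -3.88 at 88 h (mean -4.15 ± 0.13, limma adjusted p = 0.00202, mean fold 17.7 lower). Of 16 genes for spore formation and division, 7, 11 and 10 were at least 2-fold lower at 48, 64 and 88 h, with medians of -0.94, -1.86 and -1.33 (percentiles 0.01, 0 and 0). By limma 12 fell (13 adjusted over the list alone), 3 without the 64 h array and 6 without the 88 h array. The sigma factor gene whiG (SCO5621) had -2.24, -2.12 and -2.02 (adjusted p = 0.00230), whiH (SCO5819) -2.47, -3.22 and -3.33 (adjusted p = 0.00355), ssgB (SCO1541) -1.38, -3.43 and -2.87 (adjusted p = 0.0120) and the late sigma factor gene sigF (SCO4035) -0.94, -1.92 and -1.28 (adjusted p = 0.0104). The values of whiD (SCO4767), which did not pass and was chosen after its values were seen, were 0.59, -2.06 and -1.65 (adjusted p = 0.185). In the list of regulators and transporters needed for aerial growth, 6 of 13 fell, as many adjusted over the list alone, 2 without the 64 h array and 4 without the 88 h array; the medians were -0.42, -0.27 and -0.71 (percentiles 4.85, 18.8 and 0.58; -1.20, -0.98 and -1.65 with median centring). These included bldN (SCO3323), the sigma factor gene that drives chaplin genes, with -2.48, -3.33 and -3.19 (adjusted p = 0.00355), its anti-sigma factor gene rsbN (SCO3324) with -2.24, -2.65 and -2.75 (adjusted p = 0.00276), bldM (SCO4768) with -1.34, -1.66 and -1.39 (adjusted p = 0.00387) and bldB (SCO5723) with -1.23, -1.12 and -1.23 (adjusted p = 0.00389). The adpA gene (SCO2792) did not pass, with 0.68, 0.05 and -0.09 (adjusted p = 0.374). Among 19 pleiotropic antibiotic regulators, 8 fell and 1 rose, with as many in each direction adjusted over the list alone and 0 in all without the 64 h array and 6 without the 88 h array. The medians were -0.49, -0.39 and -0.20 (percentiles 0.49, 3.29 and 18.9; -0.59, -0.36 and -0.36 with median centring). The response regulator gene orrA (SCO3008) had -1.41, -1.61 and -1.70 (mean -1.57 ± 0.10, limma adjusted p = 0.00355) and nsdA (SCO5582) had -1.04, -1.54 and -1.31 (adjusted p = 0.00533), while the genes of the CutRS two-component pair went apart: SCO5862 fell, with -1.94, -1.0 and -0.52 (adjusted p = 0.0340), and SCO5863 rose, with 0.62, 1.17 and 1.37 (adjusted p = 0.0121). The afsS gene (SCO4425) did not pass, with 0.35, 0.06 and 0.65 (adjusted p = 0.104).

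The spore pigment cluster had its lowest median on the 64 h array and the gas vesicle cluster on the 88 h array. The spore pigment cluster (5785753 to 5793524) had medians of 0.55, -2.70 and -1.18 (percentiles 97.2, 0 and 0.09; 0.65, -2.94 and -1.80 with median centring). At 64 h its median was below all 10000 random lists and 7 of 8 genes were at least 2-fold lower, against 0 at 48 h and 5 at 88 h. The acyl carrier protein SCO5316 had -0.30, -4.37 and -4.03 (adjusted p = 0.0527). Over the 3 times 1 of the genes passed limma, SCO5317, with a higher mean (1.84, 0.38 and 0.89, adjusted p = 0.0473), and none did adjusted over the list alone; without the 48 h array all 8 passed, and without the 64 h or the 88 h array 0. The gas vesicle cluster (7193830 to 7199188) had medians of 0.18, 0.06 and -2.15 (percentiles 77.2, 60.1 and 0; 0.44, 0.21 and -2.25 with median centring), and 8 of 10 genes were at least 2-fold lower at 88 h against 0 at 64 h. None passed limma over the 3 times, also adjusted over the list alone, and 2 did without the 48 h array and 2 without the 88 h array. The gvpO gene (SCO6499) stood apart, with 3.01, 2.71 and -0.86 (adjusted p = 0.172). These differences between times were not tested, since each time has 1 array.

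Ribosomal protein, ATP synthase and heat shock genes were lower in the mutant. In the main ribosomal protein operon (5127609 to 5144050), 22, 14 and 2 of 25 genes were at least 2-fold lower at 48, 64 and 88 h and the medians were -2.0, -1.09 and -0.45 (percentiles 0, 0 and 1.44; -2.86, -1.70 and -1.63 with median centring). By limma 16 fell (17 adjusted over the list alone), 0 without the 64 h array. The lowest at 48 h was rpsC (SCO4708), with -2.37, -1.31 and -1.12 (adjusted p = 0.0133). All 9 genes of the ATP synthase operon fell, also adjusted over the list alone, with medians of -0.87, -0.89 and -0.61 (percentiles 0.83, 0.62 and 4.06; -1.61, -1.35 and -1.24 with median centring); 0 passed without the 64 h array. Its SCO5370 had -1.53, -1.79 and -1.09 (adjusted p = 0.00579). Of 9 chaperone and heat shock genes 7 fell, as many adjusted over the list alone and 0 without the 64 h array, with medians of -0.97, -0.81 and -0.49 (percentiles 0.82, 1.40 and 7.40; -1.66, -1.33 and -1.37 with median centring); grpE (SCO3670) had -1.24, -1.43 and -0.78 (adjusted p = 0.00815). The NADH dehydrogenase operon had medians of 0.29, 0.17 and -0.11 (percentiles 89.5, 81.4 and 46.0; -0.40, -0.31 and -0.74 with median centring). Only 2 of its 14 genes passed, SCO4562 and SCO4565 (1 adjusted over the list alone), both with a higher mean, but a mean below 0 with median centring; 3 passed without the 48 h array and 0 without the 64 h array.

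In the phosphate, acyl-CoA precursor, nitrogen and oxidative stress groups more genes rose than fell, and no phosphate gene fell. Of 12 phosphate starvation genes 5 rose, as many adjusted over the list alone, with medians of 0.31, 0.53 and 0.43 (percentiles 93.1, 99.3 and 97.8). Without the 48 h array 9 passed, without the 64 h array 0 and without the 88 h array 2. The phosphate-binding protein gene pstS (SCO4142) was the highest of them at 64 h, with 1.28, 2.37 and 1.49 (adjusted p = 0.00864). Of 17 genes of acyl-CoA and fatty acid supply, 10 rose and 1 fell (10 higher and 1 lower adjusted over the list alone), 1 in all without the 64 h array and 5 without the 88 h array. Their medians were 0.82, 0.22 and 0.46 (percentiles 99.99, 86.9 and 98.8; 0.57, -0.03 and 0.09 with median centring). The acetyl-CoA carboxylase gene SCO5535 had 2.46, 1.86 and 2.14 (adjusted p = 0.00359) and the fatty acid synthase gene SCO2388 1.91, 1.93 and 1.24 (adjusted p = 0.00542). For 13 nitrogen assimilation genes the medians were 0.72, 0.19 and 0.21 (percentiles 99.53, 82.0 and 84.1; -0.07, -0.22 and -0.60 with median centring); 6 rose and 1 fell (6 higher and 1 lower adjusted over the list alone), 0 in all without the 64 h array and 11 without the 48 h array. With median centring the means of glnII (SCO2210), glnR (SCO4159) and nirB (SCO2487), counted among those that rose, were below 0. The urease gene ureC (SCO1234), which did not pass, had 0.44, -1.14 and -1.96 (adjusted p = 0.187). The 10 oxidative stress genes had medians of 0.37, 0.48 and 0.21 (percentiles 92.3, 96.6 and 82.9; -0.14, -0.13 and -0.65 with median centring). Of these genes 5 rose and 1 fell (5 higher and 2 lower adjusted over the list alone), 0 in all without the 64 h array and 4 without the 88 h array; SCO0379, counted among those that rose, had a mean below 0 with median centring. The thioredoxin reductase gene trxB (SCO3890) had 1.06, 1.45 and 1.29 (adjusted p = 0.00465) and the peroxidase gene SCO5032 had -2.31, -1.92 and -1.66 (adjusted p = 0.00406).

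Of 5 desferrioxamine genes 4 rose, as many adjusted over the list alone, with medians of 0.63, 0.60 and 0.74 (percentiles 98.5, 97.6 and 99.3), and SCO2783 had 1.61, 1.40 and 1.44 (adjusted p = 0.00355). In the coelichelin cluster 2 of 11 genes rose and 5 fell (2 higher and 5 lower adjusted over the list alone), with medians of -0.45, -0.22 and -0.19 (percentiles 2.33, 15.4 and 14.4; -0.18, -0.05 and -0.01 with median centring); SCO0494 had -1.55, -1.35 and -1.28 (adjusted p = 0.00378). The coelibactin cluster had medians of 0.11, -0.02 and 0.11 (percentiles 79.5, 39.9 and 55.3; 0.37, 0.13 and 0.28 with median centring), with 2 of 11 genes higher and 2 lower (2 higher and 2 lower adjusted over the list alone). Both shares were below those among all 7734 genes, of which 1912 were higher and 1786 lower. The hopanoid cluster had medians of -0.11, -0.18 and 0.04 (percentiles 25.9, 25.5 and 64.0; -0.25, -0.07 and -0.01 with median centring), with 5 of 13 genes higher, SCO6765 among them (0.97, 1.34 and 1.22, adjusted p = 0.00494), and 3 lower (5 higher and 4 lower adjusted over the list alone). Its share of lower genes was near that of all genes. Of 5 chitinase genes 4 rose, as many adjusted over the list alone, with medians of 0.40, 0.53 and 0.50 (percentiles 91.1, 95.6 and 94.1; 0.66, 0.69 and 0.48 with median centring). The glycogen and trehalose cluster had medians of 0.03, -0.00 and -0.38 (percentiles 50.5, 53.9 and 23.3; -0.49, -0.47 and -0.96 with median centring), with 1 of 5 genes lower, SCO5444 (-1.65, -1.35 and -1.61, adjusted p = 0.00359), as adjusted over the list alone. Without the 64 h array, 1 gene of the glycogen and trehalose cluster passed and 0 in each of the other 5 groups. Without the 88 h array 3 desferrioxamine, 4 coelichelin, 1 coelibactin, 4 hopanoid and 2 chitinase genes passed, and without the 48 h array 3 glycogen and trehalose genes.

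Among the 12 genes beside ohkA (1699562 to 1713279), 6 fell and 2 rose over the 3 times (2 higher and 7 lower adjusted over the list alone), 0 without the 64 h array. Their medians were -0.47, -0.37 and -0.61 (percentiles 2.05, 6.73 and 1.08). The gene next to ohkA on one side, SCO1597, had -0.97, -0.98 and -0.73 (adjusted p = 0.00631), and the ribosomal protein gene rplT (SCO1598) beyond it had -1.33, -1.40 and -1.25 (adjusted p = 0.00359). On the other side, pheS (SCO1595), chosen after its values were seen, did not pass, with -0.05, -0.31 and -0.24 (adjusted p = 0.172). The lowest of the list was SCO1590, with -1.97, -1.95 and -1.40 (adjusted p = 0.00446), and the highest SCO1592, with 1.39, 1.18 and 0.93 (adjusted p = 0.00557).

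Genes outside the fixed lists were also among the most different at single times. At 48 h the highest was the cytochrome P450 gene SCO0774, with 3.56, 2.73 and 3.35 (adjusted p = 0.00307), followed by SCO5389 (3.37, 2.45 and 2.88, adjusted p = 0.00359) and the response regulator gene SCO4261 (3.36, 2.74 and 2.41, adjusted p = 0.00375). The lipoprotein gene SCO0930 had -4.23, -1.24 and 0.06 (adjusted p = 0.146), and the sigma factor gene SCO2954 had -3.78, -1.53 and 0.29 (adjusted p = 0.145). Neither passed limma over the 3 times. The reverse order was seen for genes within 2-fold at 48 h and among the lowest later. They included SCO0919 (-0.02, -4.37 and -5.58, adjusted p = 0.0706), SCO7383 (-0.27, -5.09 and -4.36, adjusted p = 0.0568), SCO3108 (-0.72, -4.02 and -5.29, adjusted p = 0.0411), the lipoprotein gene SCO7434 (-0.78, -5.03 and -4.52, adjusted p = 0.0366) and ectC (SCO1866), the gene of ectoine synthase (-0.50, -4.72 and -4.18, adjusted p = 0.0449). The membrane protein gene SCO7449 had -1.14, -5.56 and -4.69 (adjusted p = 0.0294) and the catalase gene SCO7590, with 1 spot, 0.12, -3.52 and -4.04 (adjusted p = 0.0778). Lower at all 3 times were SCO7647, a calcium-binding protein gene with 1 spot (-4.17, -3.99 and -3.62, adjusted p = 0.00202), SCO5137 (-3.83, -3.35 and -3.04, adjusted p = 0.00276) and SCO3290 (-2.89, -4.07 and -3.97, adjusted p = 0.00376). Between 48 h and 88 h, the log2 ratio moved up by at least 1 for 198 genes and down by at least 1 for 490, a size rule without a test.

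The wild-type channel alone, compared between arrays, showed which genes the parent strain switched over the same times. From 48 h to 64 h, 319 genes were at least 2-fold higher and 149 at least 2-fold lower in the wild type; by 88 h these were 417 and 260. In the mutant channel the counts were 65 higher and 218 lower at 64 h, and 112 and 395 at 88 h. The spore pigment genes had a median change from 48 h to 64 h of 3.47 in the wild type, with 8 of 8 at least 2-fold higher, and of 0.47 in the mutant, with 0. The gas vesicle genes had a median change by 88 h of 2.74 in the wild type and 0.37 in the mutant. For the ribosomal protein operon the median change by 88 h was -0.38 in the wild type and 1.04 in the mutant, where 13 of 25 genes were at least 2-fold higher. The genes of the calcium-dependent antibiotic had a median change by 64 h of -0.34 in the wild type and -1.05 in the mutant. Of the 380 genes at least 2-fold lower in the mutant at 64 h and not at 48 h, 197 were at least 2-fold higher at 64 h than at 48 h in the wild type and 3 in the mutant. The medians of these changes were 1.11 and 0.02; the selection itself favours such a difference, because the ratios and the changes share the same channels. These are differences between single arrays, with no replicate check.

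**Figure D3:**
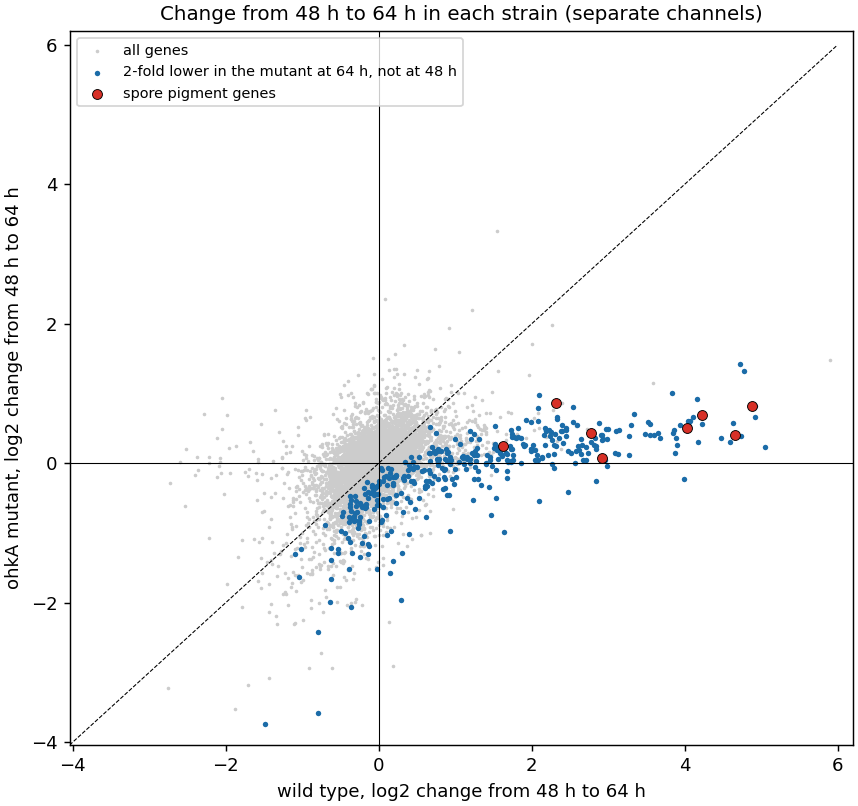
Log2 change from 48 h to 64 h in the wild type (horizontal axis) and in the mutant (vertical axis), with 1 point per gene: all genes in grey, the 380 genes at least 2-fold lower in the mutant at 64 h and not at 48 h in blue, the spore pigment genes in red; the dashed line marks equal change. The blue genes have a median change of 1.11 in the wild type and 0.02 in the mutant.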

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

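The results here had effects of opposite sign at different times; the differences were not tested, since each time has 1 array. They are the genes at least 2-fold higher at one time and at least 2-fold lower at another, and the lists, set regulators and genes named for their rank among all genes with a log2 ratio of at least 1 in size one way and 0.5 the other. Other genes also meet the second limit, whiD (SCO4767) and SCO1968 among them, and are not listed here. The test of the wild-type changes below was chosen after related results were seen.

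The spore pigment list had median log2 ratios of 0.55 at 48 h, -2.70 at 64 h and -1.18 at 88 h. The gas vesicle gene gvpO (SCO6499) had 3.01 at 48 h, 2.71 at 64 h and -0.86 at 88 h. The ROK family gene SCO6566 had 1.22 at 48 h, -1.56 at 64 h and -1.17 at 88 h, and the oxidoreductase gene SCO6570 near it had 1.12 at 48 h, -1.14 at 64 h and -0.19 at 88 h. The values of the pyruvate decarboxylase gene SCO7412 were 1.30 at 48 h, -0.88 at 64 h and -1.88 at 88 h, and those of SCO7416 were 1.09 at 48 h, -1.79 at 64 h and -1.85 at 88 h. SCO1089 had 1.35 at 48 h, -1.56 at 64 h and -1.10 at 88 h, SCO0777 had 1.09 at 48 h, -0.14 at 64 h and -1.32 at 88 h and SCO0257, with 1 spot, had 1.24 at 48 h, -1.39 at 64 h and -0.15 at 88 h. SCO6433 went the other way, with -1.59 at 48 h, 1.08 at 64 h and 0.59 at 88 h.

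Most of these follow a wider pattern, genes low in the mutant at 64 h or 88 h and not at 48 h. Spot noise of the 48 h array was tested on 365 genes with the first 48 h spot above and the 64 h scanner ratio below the 2-fold limit: the first spot had a median of -0.42, the second -0.36 and the 64 h array -1.45, so the second spot covered -5.34% of the way to 64 h, which argues against spot noise but not against an error shared by the whole 48 h array. A candidate explanation is that the wild type turns these genes on between 48 h and 64 h and the mutant does not. It was tested on the 841 genes at least 2-fold lower at 88 h, whose ratios come from an array not used for the change from 48 h to 64 h, apart from the common scaling: 193 of them, 22.9%, were raised at least 2-fold in the wild-type channel, against at most 7.25% in 1000 rotations of the gene order, and 8 in the mutant channel. The 841 genes are a wider set than the pattern, since they hold the 279 genes at least 2-fold lower at all 3 times. Most of the 841 were not raised 2-fold in the wild-type channel, so this explanation covers at most a part of them. With 1 culture per time, a difference in the age or density of the cultures stays open.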

How the results depend on the processing

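The alternatives with offset 0 and without flagged spots were chosen after seeing the data. Correction without background subtraction was not run, because the deposited signals already have it subtracted. The settings with no filter and with the median of spots moved nothing, since the filter removed no gene and no gene has more than 2 spots. No paired analysis was possible because each group has 1 array, apart from the pairing of both strains within each array, which the tested ratios already hold. Of the counts under other settings, 116 lay within 1.5 times the reported count and 4 did not. The 116 include 14 with no filter and 10 with the median of spots, which could not differ. Another 10, with the series table, repeat those with the scanner's log ratio. Leaving out 1 array gave 53 to 2003 genes higher and 91 to 2112 lower by limma, against 1912 and 1786; the low ends are without the 64 h array, and without the 88 h array the counts were 984 and 896. Each of these fits has 1 residual degree of freedom, so a gene's own spread is the difference between the 2 times kept. Without the 64 h array these are 48 h and 88 h, whose ratios correlated least across genes (r = 0.669). The pair of 48 h and 64 h had r = 0.754 and that of 64 h and 88 h r = 0.900. The low counts without the 64 h array therefore do not show that the calls rest on that array. Other causes of the difference between the fits were not tested. All 144 genes called without the 64 h array were among those called with it.

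Among results past their thresholds, signs turned only with median centring in place of loess. The nitrogen list at 48 h had a median of -0.0677, and nirB (SCO2487) had -0.53 at 88 h and a mean of -0.14. The means were -0.0597 for glnII (SCO2210), -0.0869 for glnR (SCO4159), -0.22 for SCO4562 and -0.0750 for SCO4565. For SCO0379 the mean was -0.28, with -0.40 at 88 h. Median centring differs from loess only in leaving the trend of the ratio with brightness in place. The origin of that trend was not tested. Of the comparisons of 1 gene's mean under 1 other setting, 3114 kept their side of the limma threshold and 127 gained it. A further 204 lost it with the sign kept and 6, the means above, lost it with the sign turned. The 3114 include 247 with no filter and 247 with the median of spots, which could not differ. Of the losses with the sign kept, 137 were without the 64 h array and 41 without the 88 h array. Of the list medians, 515 moved by less than the median spot SD, 213 by more, and 1 of those outside the middle 95% of random lists turned. The 515 include 81 with no filter and 81 with the median of spots, which could not differ. List medians inside the middle 95% also turned with median centring. Signal over background limits dim genes: the median signal-to-noise score of the wild-type channel was 20.2, 24.8 and 37.7 at 48, 64 and 88 h, against 174, 232 and 398 in the mutant channel.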

Other observations

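The groups in this paragraph and the next were chosen after their values were seen. Runs of at least 4 neighbouring genes, all at least 2-fold lower, numbered 20, 19 and 22 at 48, 64 and 88 h, against at most 5 in 1000 shuffles of the gene order at any time. Shuffling separates the genes of an operon, so any array with changed operons would exceed it, and the comparison says nothing particular to this mutant. Higher runs numbered 14, 3 and 3, against at most 2 at any time, and 2 of those at 88 h belong to the actinorhodin region, on either side of SCO5082. Those at 48 h hold several pieces of the calcium-dependent antibiotic cluster and of the region SCO4242 to SCO4263, so the runs are not counts of separate regions. One higher region, SCO4242 to SCO4263 (4648427 to 4679338), encodes a phage tail-like contractile injection system: its 22 genes had medians of 1.99, 1.34 and 1.09, with 17, 13 and 13 at least 2-fold higher and 18 past limma. The rar conservon, SCO1626 to SCO1630 (1740065 to 1744680), an operon of a sensor kinase-like protein and a small GTPase, was lower at each time, with medians of -2.65, -2.59 and -2.64, and all 5 genes passed limma. The nitrate reductase genes SCO4947 to SCO4950 had medians of -2.31, -1.20 and -1.30. The terpene odorant genes of geosmin (SCO6073) and methylisoborneol (SCO7700 and SCO7701) had -1.37, -1.06 and -0.93 (adjusted p = 0.00588), -1.65, -0.76 and -1.59 (adjusted p = 0.0111) and -3.11, -2.51 and -2.01 (adjusted p = 0.00462).

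The ectoine operon SCO1864 to SCO1867 (1998468 to 2001804) had medians of -0.12, -3.20 and -2.81; its median change by 64 h was 3.06 in the wild type and -0.00 in the mutant. The genes around the osmotic stress sigma factor sigB, SCO0595 to SCO0601, had -0.06, -1.03 and -1.67, and the gas vesicle region SCO0649 to SCO0657 had -0.16, -2.37 and -1.74. The iron superoxide dismutase genes SCO0999 and SCO2633 were higher at each time, with 2.73, 2.43 and 2.58 (adjusted p = 0.00202) and 2.82, 2.53 and 2.68 (adjusted p = 0.00202); their probes are nearly identical, so the 2 genes cannot be separated. The nickel superoxide dismutase gene sodN (SCO5254) had -0.08, -0.84 and -0.83 (adjusted p = 0.0632), and of the nickel transporter genes SCO6451 to SCO6455 only SCO6451 was at least 2-fold higher, with 1.48, 1.5 and 1.06 (adjusted p = 0.00501).

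The tests of the base composition, of sign patterns and of rotations below were chosen after the results were seen. Limma called 3698 genes over the 3 times, 2725 of them with a mean under 2-fold. A dye effect set by the base composition of the probes explained 5.72% to 7.51% of the variance of the log2 ratios; after its removal 81.4% of the calls were still made, 3012 genes, which argues against it as the whole cause. A dye effect of single probes stays open: 0 arrays have swapped dyes, so it cannot be told apart from an effect of the mutant, and it could account for many of the small ratios. Of the 4 sign patterns of the 3 arrays, 1, the real one, gave as many calls, 3698 against at most 0, but so few patterns cannot give a share under 0.05.

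Genes at least 2-fold higher at 88 h made up 7.28% of the 4412 genes in the chromosome's core (1500000 to 6400000) and 2.59% of the 3322 genes in the arms, an excess of 4.69 percentage points, against 0.963 at 48 h and 2.41 at 64 h. Within 10 bins of probe brightness the 88 h excess was 2.78 points, so brightness could account for part of it. Without the 4 fixed antibiotic lists it was 4.13, which argues against these lists alone. A difference as large as the full excess was reached in 2669 of 7733 rotations of the gene order. Rotation keeps runs of neighbours and larger-scale order alike, so it does not single out either, and the cause of the excess stays open. The lower genes did not differ in one direction: they made up 10% of the core and 5.78% of the arms at 48 h, 10% and 9.51% at 64 h, and 9.61% and 12.6% at 88 h. Differences as large were reached by 12, 4341 and 4081 of 7733 rotations.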
